A study of Mus musculus with 2 samples.

How the data were processed

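H3K9me3, trimethylation of histone H3 at lysine 9, is a chromatin mark found at silent genes and repeats. It was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in intestine of C57BL/6N-derived mice (B6NTac;B6NCrl/Lap) at postnatal day 0. Per the labels, there were 2 biological replicates, each of tissue pooled from males and females. Replicate 1 came from 15 mice and 1 technical replicate, and replicate 2 from 2 technical replicates. The library size range was 300 to 500 for both, per the labels. The series holds a single group, so no comparison between conditions was made.

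Per the labels and the lists that accompany the deposited files, there were 4 peak lists on the mm10 build in the narrowPeak format. One was called in each replicate, one on both replicates pooled, and one is a replicated list derived from the other lists. The rule by which a pooled peak became replicated, the peak caller, its threshold and the aligner are not given in the sources used here. The signal value of each peak is the deposited measure of enrichment from the authors' peak caller, and what it is relative to is not stated. The deposited −log10 p and −log10 q values and the display score (at most 1000) are likewise the authors' values per peak. The signal and −log10 values were used only to describe, rank or filter peaks within a list and to correlate overlapping peaks of the replicates, and the display score and summit position were not used. Signal tracks and control libraries were not analysed here. Read depth is unknown from peak lists, so no interval that needs it is given.

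The replicate and pooled lists were permissive, and the replicated list was stricter. At a q of at most 0.01 stood 6.17% of the replicate 1 peaks, 16.3% of the replicate 2 peaks, 28.7% of the pooled peaks and 73.6% of the replicated peaks. Each of the 8287 replicated peaks was checked to be an unchanged pooled peak. Gene positions came from GENCODE M21 and sequence from GRCm38.p6, the assembly mm10 stands for, and every peak ended within the length of its chromosome. Soft-masked bases of the reference were taken as repeats, and the masking program is not given in the sources used here. Coordinates are 1-based.

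Positions were tested against 1000 random lists per test. In the main test, all peaks of a chromosome were shifted by 1 random distance around the chromosome, with assembly gaps of 100 bp or more removed, which keeps widths and spacing. Domains were tested against peaks placed independently within their chromosome. Scaffold peaks stayed in place in the overlap test and were left out of the tests on genes, domains and composition. The smallest p was 0.002 in two-sided and 0.001 in one-sided permutation tests. Benjamini-Hochberg adjustment ran over the 4 annotation classes and over the 15 gene lists. Overlap meant at least 1 bp. Annotation classes used all annotated genes, with promoters 1 kb on either side of a start site, taken before exon, intron and intergenic sequence, and each peak was placed by its midpoint. A gene was called marked when its body overlapped a replicated peak. Domains joined replicated peaks no more than 10 kb apart. A chromosome was called high or low only if both replicates lay over 1.5 times above or below their genome-wide value. These permutation p-values measure placement of peaks in these libraries, not variation between animals.

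The gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the protein-coding genes at or nearest to the 20 replicated peaks of highest signal value on numbered and sex chromosomes, the 20 genes with most covered bp, up to 4 marked members with most covered bp per list, and the genes of the 10 domains with most covered bp. Zinc finger genes were taken by symbol (Zfp, Znf, Zscan, Zkscan and a few others), so members with other symbols are missed.

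Alternatives covered stricter overlap, a −log10 q of at least 2, the stronger part of each list by median signal value, other random placements, other promoter widths, gene flanks, cover minimums and merge distances, random genes matched on length, and the pooled list. Leaving out a replicate meant using the other replicate's own list alone. Added after the data were seen were first exons, merged loci, protein-coding genes only for the annotation classes, replicated peaks drawn from the pooled list, lists without X or without the 100 peaks of highest −log10 p, and peaks of unique sequence. The last kept peaks in which at least 90% of the 31-base words occurred once in the assembly on either strand, chromosomes and unplaced contigs included.

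The gene-list test was checked on simulated data. Of 450 tests on shifted copies of the replicated list, 2.22% had p below 0.05. These copies were drawn by the same shifts as the test. The share therefore checks the computation, and not how well shifts stand for real peaks. With peaks planted in 20% of the 423 zinc finger genes, the list was called in 10 of 10 simulated lists. With peaks planted in 30% of the 18 endothelium and blood genes, it was likewise called in 10 of 10. Peaks were planted only to raise a list, so the power to call a list below shifted peaks was not tested. The domain count returned 50 of 50 planted domains, and the overlap 20.2% where 20% was planted. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.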

Results

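H3K9me3 was mapped in whole intestine of newborn mice, a mixture of epithelium, mesenchyme, muscle, enteric nerves, vessels and blood. Peaks were called in 2 biological replicates of pooled tissue. Replicate 1 held 27479 peaks covering 7.32 Mb and replicate 2 held 21130 peaks covering 6.58 Mb. The pooled list held 39366 peaks, and the replicated list 8287 peaks covering 4.42 Mb. The median peak was 230 bp wide in replicate 1, 259 bp in replicate 2 and 441 bp in the replicated list. The median signal value, the authors' enrichment measure, was 2.99 in replicate 1 and 3.07 in replicate 2. The sequencing depth behind the lists is unknown. With 1 group in the series, the comparisons were between the replicates, between the lists, and between peaks and the genome.

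The 1st question was how far the replicates placed H3K9me3 at the same sites. In replicate 1, 4837 peaks (17.6%) overlapped a replicate 2 peak, against a mean of 1.21% for shifted peaks. In replicate 2, 4626 peaks (21.9%) overlapped a replicate 1 peak, against 1.44% for shifted peaks. Both shares lay above all 1000 shifts (one-sided permutation test, p = 0.001, the smallest possible). On numbered and sex chromosomes alone, where no scaffold peaks stayed in place, the folds over shifted peaks were 34.4 and 33.0, and with scaffolds 14.6 and 15.3. Most peaks of either replicate were thus not called in the other, and with a reciprocal overlap of at least 50% the shares were 8.82% and 11.5%. Across the 4837 overlapping pairs the signal values had a Spearman correlation of 0.214 (bootstrap 95% interval 0.184 to 0.241) and a Pearson correlation of 0.288 on the log2 scale. These values describe peaks of these libraries, which are not independent replicates. With peaks at a −log10 q of at least 2 only, 35.7% of replicate 1 peaks were overlapped against 5.96% for shifted peaks, and 16.8% of replicate 2 peaks against 2.58%, with scaffold peaks kept in place. The Spearman correlation was 0.559 over 604 pairs of these peaks and 0.191 over 2421 pairs of the stronger peaks by signal value.

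The replicated list held 21.1% of the pooled peaks (8287 of 39366, exact 95% interval 20.7% to 21.5%, counting error only). Replicated peaks had a median signal value of 3.13 and a median width of 441 bp, and the other pooled peaks 2.53 and 251 bp. A replicate 1 peak overlapped 74.0% of the replicated peaks, a replicate 2 peak 77.0%, and peaks of both replicates 54.7%. Among the other pooled peaks, 0.412% overlapped peaks of both replicates. At a −log10 q of at least 2, 54.1% of pooled peaks were replicated, and among the stronger peaks by signal value 35.0%.

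Chromosomes 7 and 17 carried the densest H3K9me3 in both replicates. Chromosome 7 had 17.7 peaks per Mb in replicate 1 and 15.0 in replicate 2, which was 1.72 and 1.90 times the respective genome-wide density. Chromosome 17 had 17.0 and 13.9 peaks per Mb, or 1.65 and 1.76 times. Both carry many zinc finger and vomeronasal receptor genes of the lists, 104 and 154 on chromosome 7 and 46 and 45 on chromosome 17. Chromosome 13, with 43 and 35 such genes, had 0.914 and 1.01 times the genome-wide density in replicates 1 and 2. Whether these genes account for the density was not tested. Y was low in both replicates, with 6 peaks in replicate 1 and 12 in replicate 2. The densities were not corrected for mappability or for the share of males in the pools. Few peaks on Y thus need not mean little of the mark there. X differed between the replicates, with 1133 peaks (6.93 per Mb) in replicate 1 and 179 (1.10 per Mb) in replicate 2. The density in replicate 1 was 6.33 times that in replicate 2 on X, and between 1.18 and 1.43 times on the numbered chromosomes. Of the replicate 1 peaks on X, 27.0% overlapped a pooled peak and 4.68% a replicate 2 peak, against 57.3% and 17.6% on the numbered chromosomes. Of the replicate 2 peaks on X, 71.5% overlapped a pooled peak, against 70.8%. With 2 replicates no test of single chromosomes was made. X met the rule for a low chromosome as well when peaks of a −log10 q of at least 2 or covered bp were used, or replicate 2 alone.

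**Figure D1:**
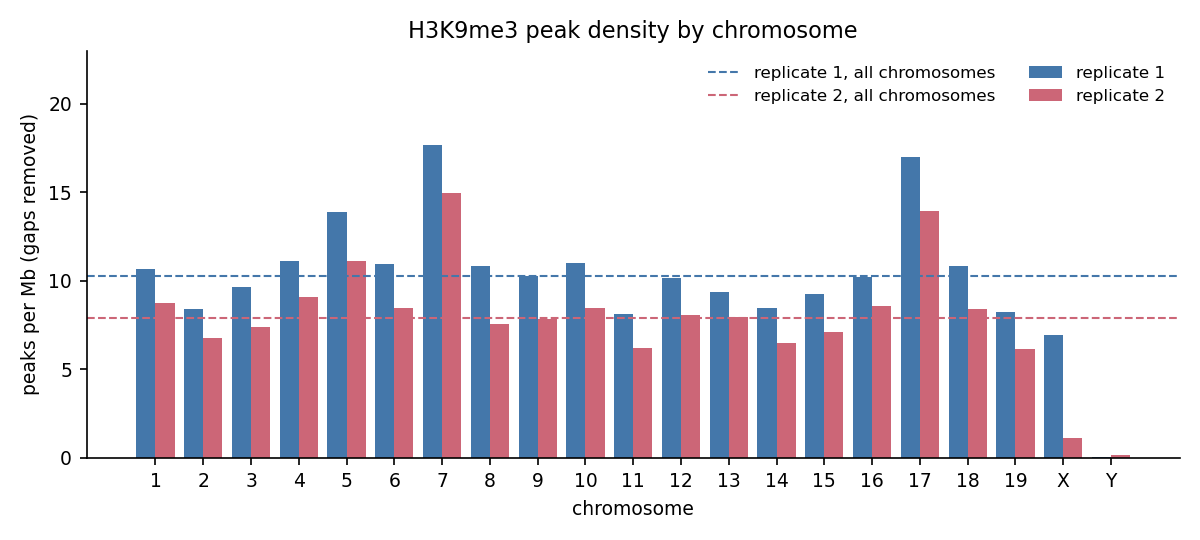
Peaks per Mb of gap-free sequence (vertical axis) on each chromosome (horizontal axis) in replicate 1 and replicate 2, with dashed lines at each replicate's density over all chromosomes. Chromosomes 7 and 17 stand above both lines in both replicates, and X has 6.93 peaks per Mb in replicate 1 and 1.10 in replicate 2.

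Replicated peaks lay outside genes and in exons more often than shifted peaks, and in introns less often. Intergenic sequence held 56.6% of the 8112 replicated peaks on chromosomes, against 49.9% for shifted peaks (adjusted permutation p = 0.0027, two-sided permutation test). Introns held 30.1% against 40.1% (adjusted permutation p = 0.0027), exons 5.60% against 3.48% (adjusted permutation p = 0.0027) and promoters 7.69% against 6.54% (adjusted permutation p = 0.01). The promoter share depended on the definition: with protein-coding genes only, a choice made after the data were seen, it was 3.42% against 4.10% (adjusted permutation p = 0.048), and with 2.5 kb 15.4% against 14.3% (adjusted permutation p = 0.132). It was also below shifted peaks in each replicate's own list, at 5.83% in both, and in the pooled list, at 5.42%, where the exon share was 3.40% against 3.44%.

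The peaks had a mean GC content of 45.0%, against 42.1% for peaks shifted around their chromosomes (two-sided permutation test, p = 0.002). Their soft-masked share, which covers annotated repeats, was 34.7% against 33.8% (permutation p = 0.15). In the replicates' own lists the soft-masked share was below shifted peaks, at 31.9% against 34.1% in replicate 1 (permutation p = 0.002) and 32.8% against 33.8% in replicate 2 (permutation p = 0.02). Mappability was not part of the shifts, so these tests cannot tell whether H3K9me3 is enriched or depleted at repeats. Repeated sequence was also measured with the words used above to define unique sequence. In the replicated list a mean of 8.79% of words per peak occurred more than once, against 17.6% in a shifted copy. The medians went the other way, at 4.28% and 1.02%.

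Peaks were grouped into domains. The 8112 peaks merged into 5899 domains, of which 138 held 5 or more peaks, and none of the 1000 placed lists held more than 2 such domains (one-sided permutation test, p = 0.001). The placed lists scatter adjacent peaks independently. The test therefore cannot tell separate peaks that cluster from a single enriched stretch that was called as several peaks. These 138 domains held 15.5% of the peaks, and peaks of both replicates lay in every one of them. As the replicated list was derived from the other lists, this is no independent evidence. At least 1 gene of the zinc finger list lay in 34 of the 138 domains, and 55 held no protein-coding gene. The count was 347 in replicate 2 alone and 408 in replicate 1 alone, whose lists are longer, and 855 in the pooled list and 68 among the stronger peaks by signal value.

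The domain with most covered sequence lay over the gamma protocadherin genes, at chromosome 18 (mm10) from 37662395 to 37771289, with 51 replicated peaks covering 46.2 kb. The next, at chromosome 1 from 88211470 to 88253178, had 25 peaks covering 33.0 kb (79.1% of its span) over the shared 3′ part of the Ugt1a genes, which encode glucuronosyltransferases of detoxification, and over Mroh2a. A domain of 19 peaks at chromosome 1 from 88277331 to 88310894 lay beside it, over Hjurp and Trpm8, the cold-sensing ion channel gene. A domain at chromosome 17 from 13191253 to 13238530 covered Smok2a and Smok2b, sperm motility kinase genes, with 21 peaks. Zinc finger genes lay in the domains at chromosome 10 from 82047147 to 82069938 (Zfp873, 17 peaks) and chromosome 4 from 146446975 to 146502261 (Zfp992 and Zfp981, 21 peaks). The other 4 of the 10 domains with most covered bp overlapped no protein-coding gene. They lay on chromosome 4 from 121998375 to 122051373 and from 3050622 to 3091144, on X from 31730912 to 31776585, and on chromosome 16 from 3231507 to 3282383.

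Of 21938 protein-coding genes, 1559 (7.11%) were marked. Among the 15 lists, 5 were marked above shifted peaks: C2H2 zinc finger genes, vomeronasal receptors, clustered protocadherins, imprinted genes and other clustered multigene families. Against peaks drawn at random from the pooled list, a comparison added after the data were seen, only zinc finger genes of the 5 were called (1.37 times, adjusted permutation p = 0.03). The other 4 lay between 0.949 and 1.04 times, each with an adjusted permutation p of 1.0. This comparison asks only whether replicated peaks differ from pooled peaks. In the pooled list itself the folds over shifted peaks were 1.68 for vomeronasal receptors, 2.02 for protocadherins and 2.12 for imprinted genes (adjusted permutation p = 0.0075 for each). Multigene families had 1.36 (adjusted permutation p = 0.0949).

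**Figure D2:**
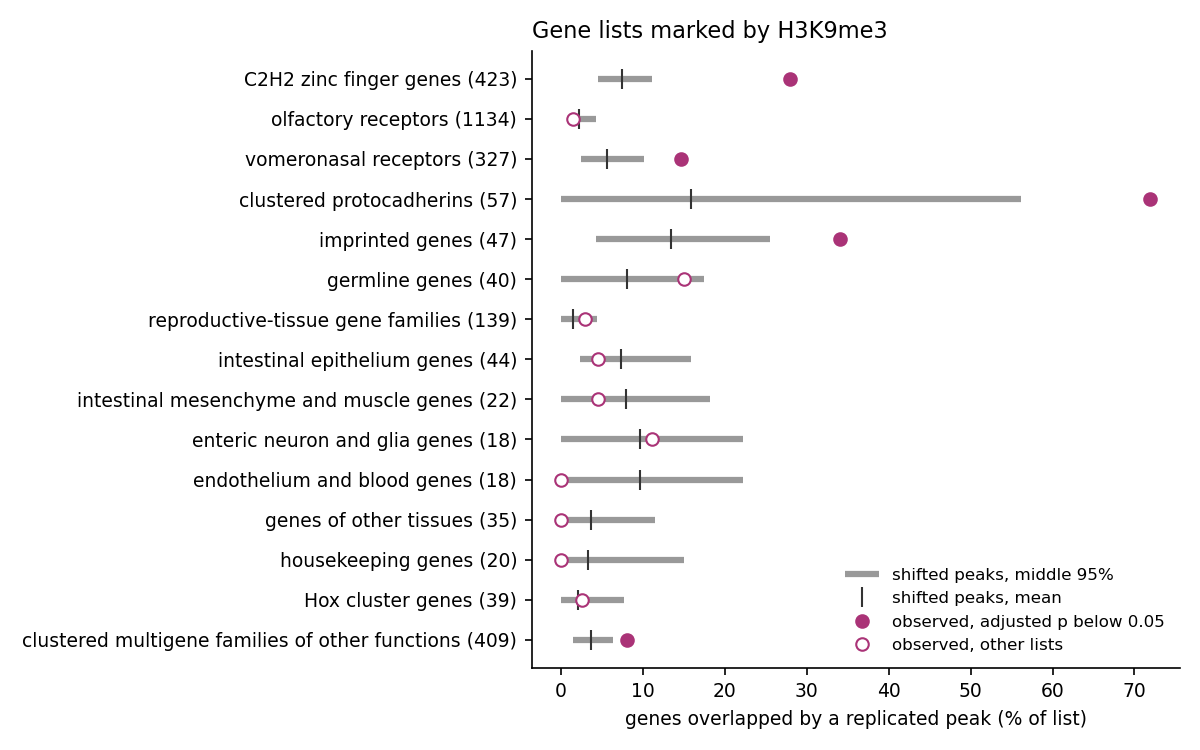
Share of each list's genes overlapped by a replicated peak (horizontal axis, percent; circles, filled where the adjusted p is below 0.05), with the mean (tick) and middle 95% (grey bar) of 1000 shifted peak lists. List sizes are in parentheses. Zinc finger genes (27.9%), vomeronasal receptors (14.7%), protocadherins (71.9%), imprinted genes (34%) and other multigene families (8.07%) lie beyond their grey bars.

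C2H2 zinc finger genes, a large family of DNA-binding repressors often found in tandem groups, were the group marked on most chromosomes. Of 423 genes, 118 (27.9%) were marked against a mean of 31.4 for shifted peaks, or 3.76 times (adjusted permutation p = 0.0075, two-sided permutation test). The marked genes lay on 18 chromosomes, with 25 on chromosome 7, 14 on chromosome 17 and 14 on chromosome 4. Zfp873 (chromosome 10, 82048123 to 82064745) had 74.1% of its 16623 bp covered. Its highest signal value was 5.17 in replicate 1 and 6.66 in replicate 2. Zfp981 on chromosome 4 had 12832 bp covered by 22 peaks, Zfp110 on chromosome 7 had 10584 bp covered by 8 peaks, and Zfp936 on chromosome 7 had 9298 bp covered by 18 peaks. The fold over shifted peaks was 1.89 in replicate 1 alone and 2.24 in replicate 2 alone (adjusted permutation p = 0.015 in both), and 6.44 with at least 500 bp covered.

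The clustered protocadherin genes, which encode cell-surface proteins of neurons and lie in 3 neighbouring groups on chromosome 18, were marked in 41 of 57 gene records (71.9%) against 9.02 for shifted peaks (4.55 times, adjusted permutation p = 0.0075). The gamma group had 51 replicated peaks covering 46239 bp, the beta group 27 covering 15099 bp and the alpha group 12 covering 4428 bp. Pcdhga1, whose body runs from 37661793 to 37841873, had 25.7% of it covered. Its highest signal value was 5.44 in replicate 1 and 5.89 in replicate 2. Pcdhga2, Pcdhga3 and Pcdhgb1 had 44996, 44705 and 43849 bp covered. These bodies are nested and share their 3′ exons, as do the readthrough models Gm42416, Gm37013 and Gm37388, so 1 peak can mark many genes. Counted by first exons, a choice made after the data were seen, 34 were marked against 0.635 for shifted peaks (adjusted permutation p = 0.0075), and as merged loci 12 against 0.965 (adjusted permutation p = 0.0225). In replicate 1 alone the fold was 2.13 (adjusted permutation p = 0.015) and in replicate 2 alone 2.64 (adjusted permutation p = 0.03). Of the 20 genes with most covered bp, all but Mroh2a (20563 bp) and Trpm8 (14835 bp) were gamma protocadherin genes or these 3 readthrough models.

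**Figure D3:**
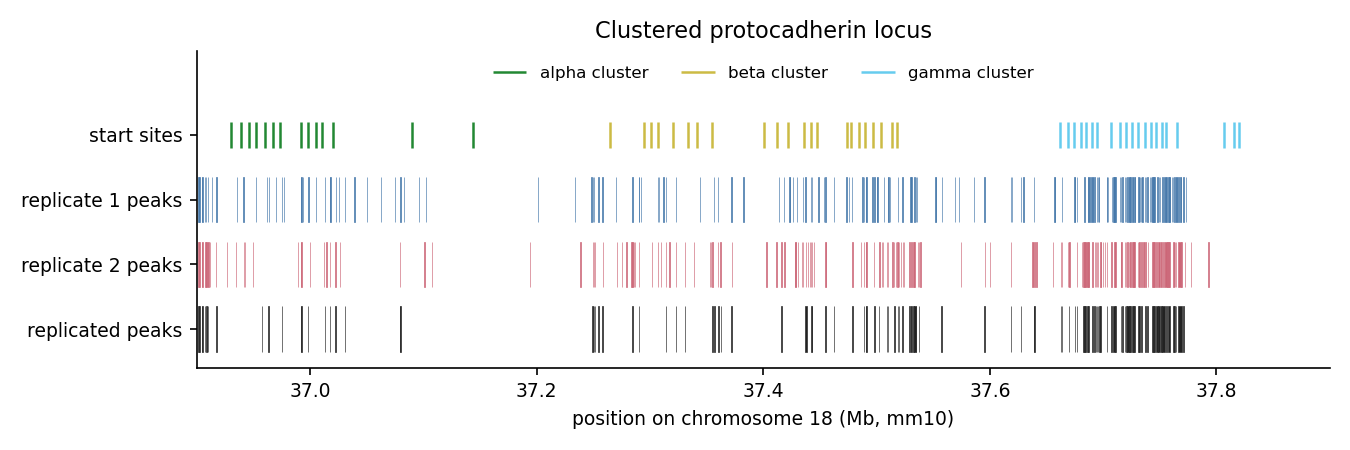
Position on chromosome 18 (horizontal axis, Mb, mm10) of the first annotated start site of each clustered protocadherin gene (top row, coloured by group) and of peaks in replicate 1, replicate 2 and the replicated list. Peaks are drawn to scale with a thin outline, and they are densest over the gamma group, where 51 replicated peaks cover 46239 bp.

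Vomeronasal receptors, which detect pheromones, were marked in 48 of 327 genes (14.7%) against 18.1 for shifted peaks (2.65 times, adjusted permutation p = 0.0075). On chromosome 7 lay 26 of them and on chromosome 17 lay 18. Vmn1r73 had 2835 bp covered by 6 peaks, and its highest signal value was 4.08 in replicate 1 and 4.86 in replicate 2. Vmn2r59 had 2362 bp covered by 6 peaks, and Vmn1r42 and Vmn1r43, whose bodies overlap, had the same 1720 bp. Near start sites alone, 10 were marked (1.89 times, adjusted permutation p = 0.411), and in first exons 9 (3.30 times, adjusted permutation p = 0.0839). In replicate 1 alone the fold was 1.65 (adjusted permutation p = 0.024).

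Olfactory receptors, the largest list, did not pass the test, with 16 of 1134 marked (1.41%) against 24.5 for shifted peaks (adjusted permutation p = 0.599). Olfr1349 on chromosome 7 had 1074 bp covered by 2 peaks, Olfr869 558 bp, Olfr853 527 bp and Olfr77 487 bp. Olfr869 had no peak in the list of replicate 2. The count was below random placement within chromosomes (0.536 times, adjusted permutation p = 0.015). It was above shifted peaks, without passing the test, in each replicate's list, in the pooled list and with 5 kb flanks.

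Imprinted genes, expressed from 1 parental copy, were marked in 16 of 47 genes (34%) against 6.28 for shifted peaks (2.55 times, adjusted permutation p = 0.012). Gnas, which encodes a G protein subunit, had 3165 bp covered by 5 peaks (chromosome 2, 174284320 to 174346744). Mest had 2452 bp covered by 4 peaks, Grb10, a growth factor receptor adaptor gene, 2297 bp by 4, and Kcnq1, a potassium channel gene, 2038 bp by 3. The highest signal value of Mest was 3.36 in replicate 1 and 5.38 in replicate 2. With start sites alone, 12 were marked against 1.18 (adjusted permutation p = 0.01). In replicate 1 alone the fold was 1.69 (adjusted permutation p = 0.02), and the call was not made in replicate 2 alone (1.66 times, adjusted permutation p = 0.0674) or against random placement within chromosomes (1.70 times, adjusted permutation p = 0.0599).

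Other clustered multigene families were marked in 33 of 409 genes (8.07%) against 14.9 for shifted peaks (2.22 times, adjusted permutation p = 0.0075). The most covered were Ugt1a7c (7777 bp), Ugt1a10 (6811 bp), Ugt1a8 (6811 bp) and Ugt1a6b (6810 bp), which share the same 3′ exons. Counted as merged loci, 25 were marked (1.85 times, adjusted permutation p = 0.0779), and in replicate 2 alone 50 (1.499 times, adjusted permutation p = 0.0779). Among the stronger peaks by signal value 12 were marked (1.39 times, adjusted permutation p = 0.921), and the call was also lost with the pooled list, 5 kb flanks, start sites, first exons and placement within chromosomes.

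Few genes of the cell types of intestine were marked, shifted peaks also gave few, and no list of them passed the test. Of 44 intestinal epithelium genes 2 were marked, against 3.22 for shifted peaks (adjusted permutation p = 0.981): Dclk1, a marker of tuft cells, with 1286 bp covered, and Lgr5, a marker of intestinal stem cells, with 974 bp. Of 22 mesenchyme and muscle genes 1 was marked, against 1.74 for shifted peaks (adjusted permutation p = 1.0): Ano1, a chloride channel gene of pacemaker cells, with 587 bp. Of 18 enteric neuron and glia genes 2 were marked, against 1.72 for shifted peaks (adjusted permutation p = 1.0): Gfra1 with 859 bp and Chat, the gene of the acetylcholine-synthesising enzyme, with 369 bp. Chat had no peak in the list of replicate 2. None of 18 endothelium and blood genes (1.74 for shifted peaks, adjusted permutation p = 0.599), 35 genes of other tissues (1.28, adjusted permutation p = 0.797) or 20 housekeeping genes (0.65, adjusted permutation p = 1.0) was marked. For these 3 lists 0 is the lowest possible count, so the test could not call them below shifted peaks. Of 39 Hox genes 1 was marked (adjusted permutation p = 1.0): Hoxc5, with 284 bp and no peak in the list of replicate 2.

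Germline genes were marked in 6 of 40 (15.0%) against 3.23 for shifted peaks (1.86 times, adjusted permutation p = 0.485). Meioc, a gene of meiosis, had 1207 bp covered, Mov10l1, of the piRNA pathway, 915 bp, Ddx4, a germ cell helicase gene, 677 bp, and Tdrd9 367 bp. By first exons alone, a choice made after the data were seen, 3 were marked against 0.205 (14.6 times, adjusted permutation p = 0.0075). Near start sites alone 3 were also marked, against 0.546 (5.5 times), and the list did not pass the test (adjusted permutation p = 0.112). Reproductive-tissue gene families were marked in 4 of 139 (adjusted permutation p = 0.599), namely Pramef8 with 600 bp, Obox8 with 483 bp, Obox6 with 426 bp and Obox1 with 311 bp. Obox1 had no peak in the list of replicate 2.

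The 20 replicated peaks of highest signal value on numbered and sex chromosomes were seen in both replicates, from whose lists the replicated list derives. By protein-coding gene models, 9 of the 20 lay in exons, 6 in introns, 1 in a promoter and 4 between genes. Genes of the zinc finger list held 5 of them: Zfp945, Zfp606, Zfp37, Zfp873 and Zfp2. The highest, with a signal value of 7.43, lay between genes on chromosome 12 from 5055929 to 5056413, 8534 bp from Atad2b. The next, at 6.88, lay on chromosome 4 from 147350227 to 147350988 in introns of the non-coding genes C230088H06Rik and Gm26624, 10314 bp from Zfp978. The 3rd, at 6.71, lay in an intron of Lyst, a lysosomal trafficking gene, on chromosome 13 from 13754980 to 13755456, and had a signal value of 2.00 in replicate 1 and 6.59 in replicate 2. A peak at the promoter of Tcfl5, a transcription factor gene, ran from 180642738 to 180643922 on chromosome 2 with 6.53 in replicate 1 and 6.71 in replicate 2. Exonic peaks also lay in 2610008E11Rik, AU041133, Plec, the gene of a cytoskeletal linker, and a gamma protocadherin exon. Intronic peaks lay in 1500009L16Rik, Tmem267, Kirrel3, Asmt on X and the protocadherin readthrough models. The remaining peaks lay 1878 bp from Orc2 and 274732 bp from Gm21863.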

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

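The tests in this part on X, on Y and on signal values were chosen after the results they measure were seen. The tests on repeated sequence and on neighbouring zinc finger genes were set before theirs. As the series has 1 group, the design gave no biological explanation to test.

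Peaks on contigs outside the assembled chromosomes were left out of the comparisons on genes. The replicated list held 175 peaks on 20 of the 44 unplaced and unlocalized contigs, or 32.8 per Mb against 3.06 per Mb on chromosomes (10.7 times). The ratio was 4.80 in replicate 1, 5.34 in replicate 2 and 3.33 in the pooled list. The contig JH584304 held 44 of the 175 replicated peaks, with a −log10 p of up to 93.2. Their median signal value was 2.78, against 3.13 in the whole replicated list. The contig with the next most peaks, GL456393, held 29 with a median of 3.22. Repeated words were not measured for contig peaks and control libraries were not analysed. Whether sequence present in several copies raises these counts was therefore not tested.

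The X chromosome had 6.33 times the peak density in replicate 1 that it had in replicate 2, although both pools mixed the sexes, and a longer list does not account for this, since the numbered chromosomes lay between 1.18 and 1.43. Weak calls made up most of the gap, with 1079 against 137 X peaks at a −log10 q below 2 and 54 against 42 at 2 or more. They also made up most of the numbered-chromosome peaks, with 24560 below 2 in replicate 1 and 17470 in replicate 2. Relative to the numbered chromosomes (1517 and 3244 peaks at 2 or more), X peaks were still 2.75 times as frequent in replicate 1 at 2 or more and 5.03 times over all peaks, which argues against weak calls alone (Fisher's exact test for the 2.75, two-sided, p = 1.313e-06, too small because peaks of 1 library are not independent). More males in the pool of replicate 2 stay open as a partial cause, and the size of any such effect was not measured. Y peaks below 90 Mb went the other way, 1 in replicate 1 and 6 in replicate 2 (ratio 0.132, Fisher's exact test, two-sided, p = 0.0494). That result rests on 7 peaks, and its p is too small because peaks of 1 library are not independent. The pools' sex ratios and the control libraries were not analysed here, and differences in the control stay open.

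The 100 replicated peaks of highest −log10 p included 43 on unplaced contigs, and the 3 highest were at Sfi1 and Drg1 on chromosome 11 and on JH584304, with signal values of 3.11, 3.10 and 2.92. On chromosomes these peaks had a mean of 32.2% of 31-base words found more than once in the assembly, against 8.62% in the other replicated peaks (permutation test of 57 against 8055 peaks, p = 0.0001, the smallest possible). Sequence present in several copies may thus raise their −log10 p. Stronger enrichment stays open: their median signal value, 3.91, was at percentile 91.6 of the list, but −log10 p rises with the signal value by construction. Without these 100 peaks the zinc finger, vomeronasal, protocadherin, imprinted and multigene lists were still called.

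Zinc finger, vomeronasal receptor and protocadherin genes have close copies, whose shared reads might raise all 3 counts. With peaks of unique sequence only, the fold over shifted peaks was 4.23 for zinc finger genes (102 marked), 2.76 for vomeronasal receptors (38 marked) and 5.73 for protocadherins (39 marked), each with an adjusted permutation p of 0.012. Peaks with many exactly repeated words thus do not account for the whole of the counts. The shifted peaks were not held to unique sequence, and copies that differ by a few bases can pass as unique. Shared reads are therefore not excluded, and copies missing from the assembly stay open. Neighbouring genes of the zinc finger list do not account for the whole vomeronasal count either. Of the 210 receptor genes with none within 500 kb, 24 were marked, 2.12 times shifted peaks (permutation p = 0.018). Of the 117 others, 24 were marked, at 3.54 times (permutation p = 0.012). The list misses zinc finger genes with other symbols, so neighbours of that kind stay open. For the difference between these groups, Fisher's exact test gave a two-sided p of 0.0336, which is too small because neighbouring genes are not independent.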

How the results depend on the processing

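Tests with first exons, merged loci, draws from the pooled list, protein-coding genes only, unique sequence, and without X or the 100 peaks of highest −log10 p were chosen after the data were seen. Of 339 alternative values, 273 kept the direction and the side of the threshold where there was a test, or stayed close to the reported value where there was none or a count was compared, and 37 turned direction. The 4 domain counts that moved below stayed above random placement (permutation p = 0.001). Zinc finger genes stayed above random lists and past the threshold in all 17 alternatives, from 1.37 to 6.44 times. The overlap of the replicates passed its test in all 16. The lists of cell-type genes moved on counts of 0 to 6 genes and were never called. Peak lists give no depth, so weak or absent peaks could not be told from low coverage, and mappability was not part of the random placement. No paired analysis was possible because the series has 1 group. No fold could be given for housekeeping genes against pooled-list draws, which held none. The cause of the changes below was not tested, except that longer or shorter lists change counts by construction.

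Using 1 replicate's own list gave 347 to 408 domains, 1 to 2 low chromosomes, promoter shares of 5.827% to 5.831% and soft-masked shares of 31.9% to 32.8%, both now below shifted peaks. Folds were 1.66 to 1.69 for imprinted genes, 1.498 to 1.499 for multigene families, 1.09 to 1.17 for olfactory receptors, 0.288 to 0.927 for enteric genes and 0.0 to 1.19 for Hox genes. A −log10 q of at least 2 gave a signal correlation of 0.559, a replicated share of 54.1%, 2 low chromosomes and 0.756 times for enteric genes. The stronger peaks by signal value gave a replicated share of 35.0%, 68 domains, a soft-masked share of 35.2% (permutation p = 0.048), and 0.812 times for reproductive families, 1.08 for epithelium, 0.957 for enteric and 1.39 for multigene genes. Using −log10 p gave a correlation of 0.259, and covered bp 2 low chromosomes. The pooled list gave 855 domains, promoter 5.42%, exon 3.40%, soft-masked 33.8%, and 1.08 times for olfactory, 0.804 for enteric and 1.36 for multigene genes. A promoter of 2.5 kb gave 15.4% (adjusted permutation p = 0.132), and protein-coding genes only 3.42%.

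Random placement within chromosomes gave 0.536 times for olfactory receptors, now called, 1.70 for imprinted, 0.900 for enteric and 1.57 for multigene genes. Placement in the genome gave 0.804 for reproductive families, 0.910 for enteric and 0.906 for Hox genes. Flanks of 5 kb gave 1.25 for olfactory, 1.38 for mesenchyme and 1.75 for multigene genes. Start sites alone gave 1.89 for vomeronasal, 2.23 for mesenchyme, 0.0 for enteric and 2.04 for multigene genes. At least 500 bp covered gave 1.28 for epithelium, 1.22 for mesenchyme and 0.0 for Hox genes.

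First exons gave 3.30 for vomeronasal, 14.6 for germline, 3.25 for multigene genes and 0.0 for reproductive, enteric and Hox genes. Merged loci gave 1.85 for multigene genes. Against draws from the pooled list, vomeronasal receptors had 0.962, protocadherins 1.04, imprinted genes 1.03, mesenchyme 1.05, Hox 0.927 and multigene families 0.949. Such draws compare replicated peaks with pooled peaks, and not with random positions.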

Other observations

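The tests on imprinted start sites were chosen after the gene-list counts were seen. Those on the position of peaks in zinc finger genes and on zinc finger clusters were set before their results. Each is a hypothesis tested on the data that prompted it.

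Gene types were each compared with shifted peaks after the data were seen, and not with one another. Processed pseudogenes were marked in 101 of 9940 against 39.1 for shifted peaks (2.59 times, adjusted permutation p = 0.012, two-sided permutation test over 12 gene types). Unprocessed pseudogenes were marked in 52 of 2642 against 29.2 (1.78 times, adjusted permutation p = 0.048). Transcribed unprocessed pseudogenes did not pass the test, with 18 of 253 marked against 11.1 (1.62 times, adjusted permutation p = 0.148). LincRNA genes were marked in 274 of 5854 against 255.9 (adjusted permutation p = 0.375). Protein-coding genes as a whole were marked less often than shifted peaks, 1559 against 1874 (0.832 times, adjusted permutation p = 0.012). In the multigene list, 7 Sult2a genes on chromosome 7, sulfotransferases of steroids and bile acids, were marked, with 4186 bp covered in Sult2a8 and 2356 bp in Sult2a7. They were singled out after their values were seen.

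Within zinc finger genes, H3K9me3 may favour the 3′ end. The mean relative position of peaks, with 0 at the gene's start and 1 at its end, was 0.724 in 117 zinc finger genes and 0.505 in 1416 other marked protein-coding genes (two-sided permutation test of gene labels, p = 0.0001, the smallest possible). Clustered and nested genes are not independent, so this p is too small. Gene bodies were also divided into 4 equal parts, and each peak was counted once per gene it lay in. The part at the 3′ end held 50.1% of these counts in zinc finger genes and 24.4% in the others. Nested genes among the others, such as the gamma protocadherins, share peaks, so a peak can count several times there.

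Zinc finger genes in clusters may be marked more often than solitary ones. Of 227 zinc finger genes with 3 or more others within 500 kb, 33.9% were marked, and of 122 with none 18.0% (Fisher's exact test, two-sided, p = 0.00179). Neighbouring genes are not independent, so this p is too small.

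In imprinted genes, peaks may favour start sites. Of 16 marked imprinted genes, 11 (68.8%) had a replicated peak within 1 kb of a start site of their own, against 217 of 1543 other marked protein-coding genes (14.1%; Fisher's exact test, two-sided, p = 1.166e-06). The 11 were Blcap, Cdkn1c, Gnas, Grb10, Impact, Mest, Nnat, Peg10, Peg3, Plagl1 and Sgce, named here after their values were seen. Nnat lies within Blcap and Peg10 beside Sgce, so 1 peak can count for both and this p is too small. The test is close to the count that prompted it, 12 of 47 imprinted genes marked near start sites (10.2 times shifted peaks), and is no independent evidence.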
